A study of Setaria viridis with 24 samples.

How the data were processed

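RNA was measured by sequencing in Setaria viridis, a small C4 grass used as a model for cereal crops. Per the labels, plants were grown in a mix of sand and peat, either watered or kept under drought, and 20 plants were harvested for each sample at 6 or 9 days after sowing. The shoot base was divided into a lower region, the crown, from which shoot-borne roots emerge in grasses, and an upper region, the stem. Each of the 8 combinations of region, water supply and day had 3 libraries, 1 from each of 3 biological repeats, which gives 24 libraries. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries that keep the strand of the transcript.

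The submitters' processing notes name FastQC, cutadapt and Cuffdiff, without versions. The aligner, its settings and the genome build are not given in the sources used here. The deposited data are 28 tables, 1 for every pair of the 8 groups, and each group occurs in 7 of them. Per the file headers, every table gives for each gene the FPKM value of both groups (fragments scaled to transcript length and to the number of mapped fragments), the log2 fold change between them, a p-value and a q-value. An FPKM in these tables is the authors' value for a group, and the values of the 3 libraries behind it were not analysed here. It therefore carries no standard deviation, and read depth per library is unknown.

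Checks of the tables showed how their columns were made. The deposited log2 fold changes equalled the log2 ratio of the FPKM values within 4.8e-05. A group had the same FPKM in each of its 7 tables, with 0 differing values. The authors' q-values equalled a Benjamini-Hochberg adjustment over all 531416 rows of the 28 tables jointly, within 5.3e-07. One threshold on p thus applies to every table, and the largest p of a called gene was 0.00735. The adjustment therefore limits the share of false calls over the 28 tables jointly, not within each table. In tables with few calls, such as those of drought, that share may be higher and was not measured. Counts, direction shares and overlaps of drought calls include any such false calls. The smallest deposited p-value was 5e-05, at a q-value of 0.00091, so the authors' p-values do not rank the genes that share it. Every listed row had at least 1.97 FPKM in its higher group, and between 49 and 87 genes per table were left out although a group value reached 2 FPKM. A gene that is not listed in a table was treated as not tested there. Between 17795 and 20009 genes were listed per table and 20865 in any of them.

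Gene identifiers were used as the files give them. The annotation columns held no description in any row, and 0 of the identifiers matched the 34587 genes of the reference name table. For that reason the 22 gene lists fixed before the data were examined (such as dehydrins, auxin response, cell cycle and root markers) had 0 members and gave no result. Genes are named by identifier and by the position in the files. Coordinates follow the files' own gene models, 20795 genes lay on 9 chromosomes and 70 on scaffolds. For 1550 genes the files repeat a position entry that another gene also has.

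No test on libraries was possible from group values. The design fixed before the data were examined therefore fell back on its second branch, in which genes with the authors' adjusted p under 0.05 are counted by direction. Of the 28 pairs, 12 differ in a single factor and were compared. The difference between 2 such comparisons (the interaction of drought with region or with day) was not tested, and fold changes are set side by side. The rule for named genes took the 2 largest rises and the 2 largest falls in log2 fold change per comparison, among called genes with both groups above 0 FPKM and the higher group at or above the median of the genes listed. Genes named outside this rule are said to be chosen after their values were seen.

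Calls of 2 comparisons were overlapped only where the comparisons share no library. Each overlap is given with the number expected of independent lists and the odds ratio from Fisher's exact test, two-sided. Gene sets defined by region or by age were followed into drought comparisons with no library in common, and the median log2 fold change of a set was ranked among 10000 random lists of the same size drawn within 20 bins of mean FPKM. Pairs of neighbouring listed genes called in the same direction were counted and compared with 10000 permutations of the calls within the same bins, which makes 0.0001 the smallest p these permutations can give. Overlaps, sets and neighbours were chosen after the data were seen, describe genes across the genome, and take genes as units although genes are not independent replicates. Groups without a common library still come from the same 3 repeats, and crown and stem of a day and water supply from the same harvest, whereas the expected numbers and the random lists treat them as independent. Whether both regions were cut from the same plants is not given in the sources used here. The p-values of the overlaps, of the sets and of the neighbours were adjusted by Benjamini-Hochberg within each family. Intervals of percentages are exact 95% binomial intervals and treat genes as independent. For the principal component analysis and for correlations between groups, log2(FPKM + 1) was used.

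Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data built on the 20009 genes of the day 9 crown comparison. There the adjustment recovered 16.5% of genes changed 2-fold, with 3 false calls, and 91% of genes changed 3-fold, with 11 false calls. This simulation drew differences with a set, known spread and adjusted over these 20009 genes alone, not over all tables jointly. Its numbers therefore do not measure the power or the false calls of the authors' tests. The alternatives were an adjusted p under 0.01, a minimum of a 2-fold change, genes at or above the median mean FPKM, adjustment within each table and fold changes centred on the median gene.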

Results

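The series covered crown and stem of young Setaria viridis plants, watered or under drought, at 6 and 9 days after sowing. Each of the 8 groups had 3 libraries, summarised by the authors as 1 FPKM value per gene. On the first principal component of log2(FPKM + 1), which held 60.2% of the variance, the groups ran from the watered day 6 stem at -0.51 to the drought day 9 crown at 0.57. The second component held 16.1%. Pearson correlations across genes between the drought and the watered group of the same region and day were 0.979 in the day 6 crown, 0.984 in the day 6 stem, 0.976 in the day 9 stem and 0.941 in the day 9 crown. Between day 6 and day 9 they were 0.958 in watered and 0.957 in drought stems, and 0.938 in watered and 0.940 in drought crowns, so that in the day 9 crown the drought and watered groups lay about as far apart as the days did. The farthest pair was the drought day 9 crown and the watered day 6 stem, at 0.815. The most abundant gene was Sevir.7G168800 in all 4 day 6 groups and in the watered day 9 stem, with 38641.5 FPKM in the watered day 6 stem, and Sevir.9G098200 in the other day 9 groups, with 24734 FPKM in the drought day 9 stem.

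**Figure D1:**
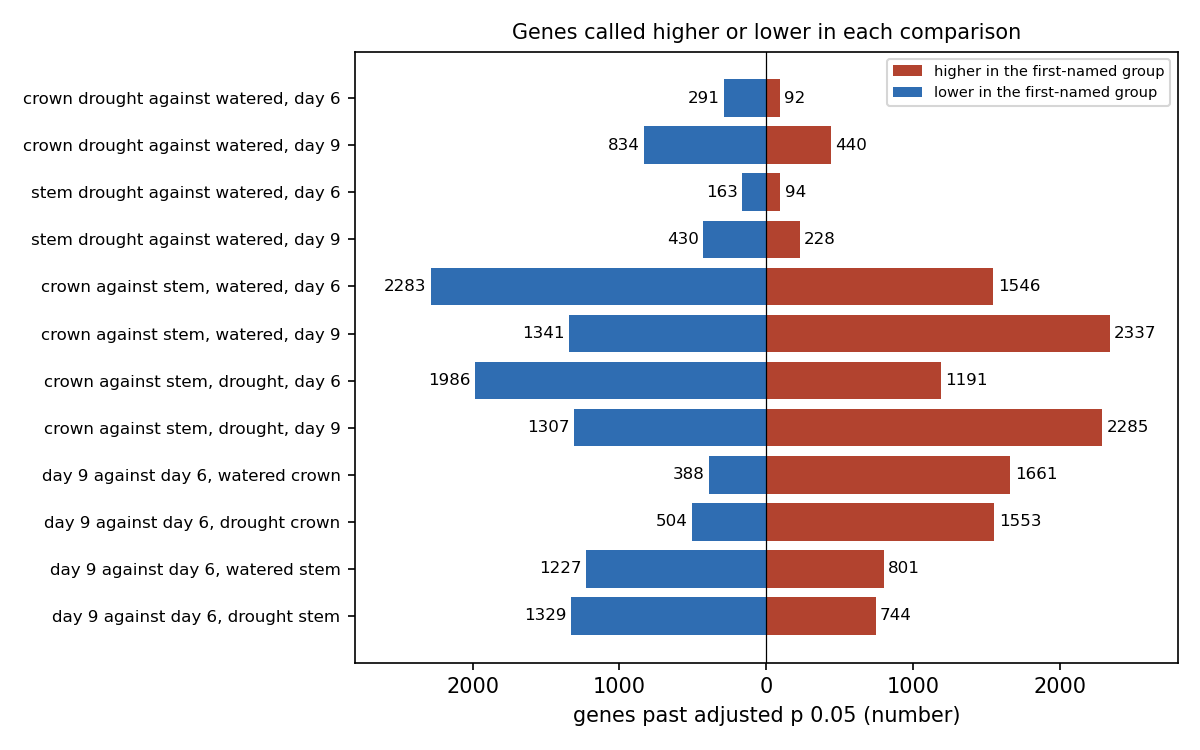
Number of genes past the authors' adjusted p of 0.05 in 12 comparisons (horizontal axis, genes), with genes higher in the first-named group to the right and genes lower in it to the left. Drought against watered gave between 257 and 1274 genes per comparison, and crown against stem between 3177 and 3829.

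Drought against watered in the crown at day 6 asked how the root-forming region responds to drought. Among called genes above 0 FPKM in both groups that met the expression minimum for naming, neighbouring genes on chromosome 5 had the largest rises. In the authors' deposited table, Sevir.5G091000 (chromosome 5, 7307464 to 7307917) stood at 97.2 FPKM under drought and 1.94 FPKM in watered plants, a log2 fold change of 5.65 (q = 0.0162). Its neighbour Sevir.5G090900 (chromosome 5, 7304309 to 7305091) stood at 118 and 4.17 FPKM, a log2 fold change of 4.82 in the authors' deposited table (q = 0.00091). The largest falls among called genes in the authors' deposited table, with at least 13.1 FPKM in the higher group as the naming rule asks, were those of Sevir.3G005700 (chromosome 3, 344049 to 345380), from 18.4 to 2.26 FPKM (log2 fold change -3.03), and Sevir.7G201700 (chromosome 7, 25622450 to 25623615), from 28.3 to 5.06 FPKM (log2 fold change -2.48), both at q = 0.00091. Of 18417 genes listed, 383 passed the authors' adjusted p of 0.05, of which 92 were higher and 291 lower under drought, so that 76.0% were lower (95% interval 71.4 to 80.2). The median log2 fold change was 1.26 among the higher and -1.26 among the lower genes. The joint adjustment over all tables does not limit the share of false calls in this list alone. Adjusted within this table alone, 95 genes passed, 27 higher and 68 lower, and Sevir.5G091000 no longer did.

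At day 9 the crown had the largest drought response of the 4 by number of genes. Sevir.7G029400 (chromosome 7, 9224001 to 9227104) rose from 0.649 to 32.4 FPKM, a log2 fold change of 5.64 in the authors' deposited table (q = 0.00091). Sevir.5G091000 again stood at 97.0 FPKM under drought, against 2.89 FPKM in watered crowns, with a log2 fold change of 5.07 in the authors' deposited table (q = 0.00167). Sevir.5G028500 (chromosome 5, 2059345 to 2061055) fell from 40.1 to 0.469 FPKM, a log2 fold change of -6.42 in the authors' deposited table (q = 0.0096). Sevir.5G164700 (chromosome 5, 15658499 to 15660216) fell from 46.8 to 0.755 FPKM, a log2 fold change of -5.95 in the authors' deposited table (q = 0.00091). Of 20009 genes listed, 1274 passed, 440 higher and 834 lower under drought (65.5% lower, 95% interval 62.8 to 68.1). Among the lower genes, 46 were listed at 0 in drought crowns, and the median log2 fold change of the others was -1.49, while that of the higher genes was 1.41.

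In the day 6 stem a gene of the same segment of chromosome 5 led the rises under the naming rule. Sevir.5G091200 (chromosome 5, 7319439 to 7320228) stood at 24.3 FPKM under drought and 2.22 FPKM in watered stems, a log2 fold change of 3.45 in the authors' deposited table (q = 0.00091). Sevir.1G012100 (chromosome 1, 939299 to 946263) rose from 11.9 to 110 FPKM, a log2 fold change of 3.21 in the authors' deposited table (q = 0.00091). The falls named by the rule were smaller: Sevir.2G057800 (chromosome 2, 4542912 to 4543464) went from 26.4 to 6.60 FPKM (log2 fold change -2.00, q = 0.00359) and Sevir.4G300400 (chromosome 4, 39295169 to 39298521), which shares its position entry with 1 other gene, from 22.1 to 6.85 FPKM (log2 fold change -1.69, q = 0.00091), both in the authors' deposited table. Of 17795 genes, 257 passed, 94 higher and 163 lower (63.4% lower, 95% interval 57.2 to 69.3). As in the day 6 crown, the joint adjustment does not limit the share of false calls in this list alone. The percentage and its interval do not account for false calls. The excess of lower genes held with a minimum of a 2-fold change (73 higher, 113 lower) but not under the 2 stricter limits on p. At an adjusted p under 0.01, 40 genes were higher and 40 lower, and adjusted within this table alone 23 were higher and 13 lower, without Sevir.2G057800.

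In the day 9 stem the same gene led the rises under the naming rule. Sevir.5G091200 rose from 0.919 to 38.7 FPKM, a log2 fold change of 5.40 in the authors' deposited table (q = 0.00728). Sevir.5G302500 (chromosome 5, 34362836 to 34363959) rose from 5.53 to 232 FPKM, a log2 fold change of 5.39 in the authors' deposited table (q = 0.00091). Sevir.6G112300 (chromosome 6, 14535788 to 14537727) fell from 14.9 to 1.26 FPKM and Sevir.3G352200 (chromosome 3, 42315206 to 42316471) from 20.4 to 1.87 FPKM, with log2 fold changes of -3.56 and -3.45 in the authors' deposited table (both q = 0.00091). Of 18145 genes, 658 passed, 228 higher and 430 lower (65.3% lower, 95% interval 61.6 to 69.0). Adjusted within this table alone, 280 passed, 99 higher and 181 lower.

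Longer runs of adjacent called genes were then listed, a step chosen after the values were seen. The 4 listed genes between 7304309 and 7320228 on chromosome 5 (Sevir.5G090900 to Sevir.5G091200) were all higher in drought crowns at day 9, with log2 fold changes from 3.53 to 5.07 in the authors' deposited table. At day 6, 3 of the 4 were called in the crown and 3 in the stem, and 2 were called in the day 9 stem, with no call in the other direction. Uncalled genes also rose in the authors' deposited tables. Sevir.5G091100 had log2 fold changes of 7.13 in the day 6 crown (q = 0.477), 1.70 in the day 6 stem (q = 0.181) and 4.93 in the day 9 stem (q = 0.415). That of Sevir.5G091000 in the day 9 stem was 4.41 (q = 0.381). On chromosome 8, the 6 listed genes between 35643963 and 35769657 (Sevir.8G220000 to Sevir.8G220700) were all higher in drought stems on both days, with log2 fold changes from 1.55 to 2.99 at day 6 and from 1.45 to 1.92 at day 9 in the authors' deposited tables. In the crown all 6 also had the higher FPKM under drought on both days, and 0 of them were called at day 6 and 1 at day 9. One of them, Sevir.8G220300, stood at 44.5 and 5.59 FPKM in drought and watered day 6 stems, and at 524 and 353 FPKM in the corresponding crowns. Whether the drought response of these genes differed between stem and crown was not tested.

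**Figure D2:**
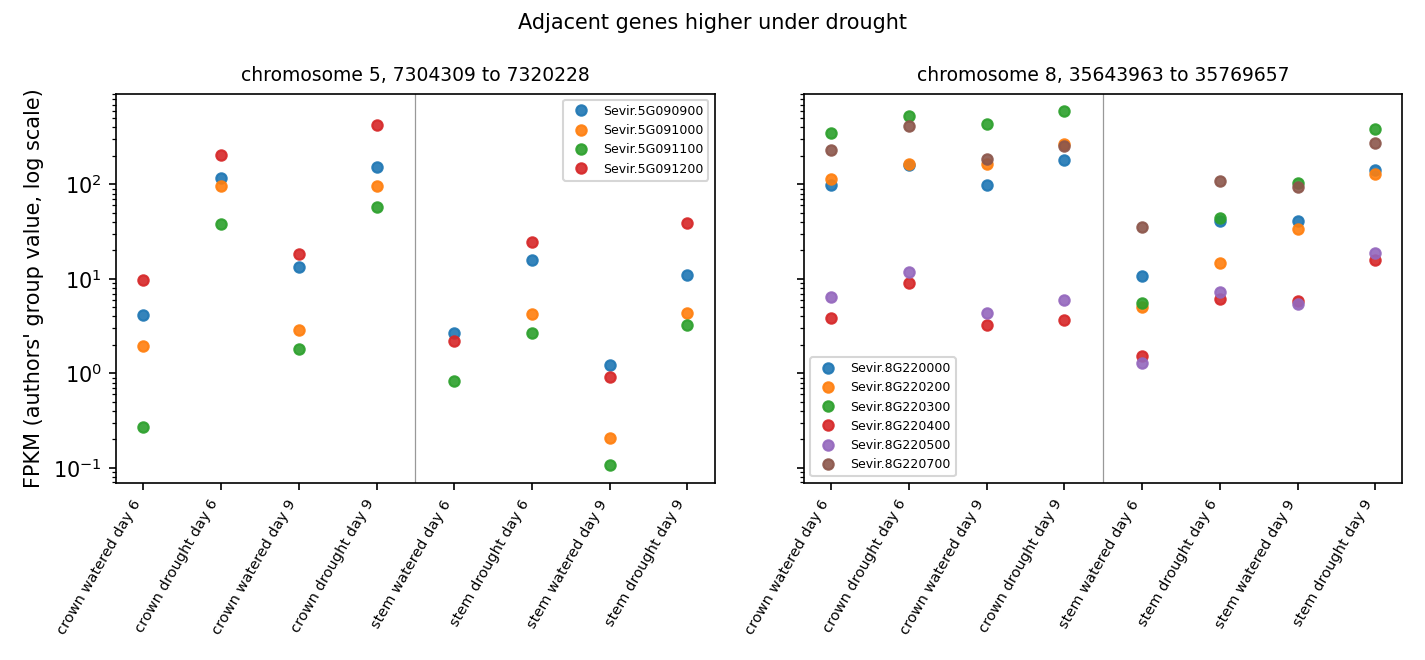
FPKM (authors' group value, log axis) of the listed genes in 2 chromosome segments, by group, with 1 point per gene and group and values of 0 left out. The 4 genes on chromosome 5 lie higher in drought than in watered groups of either region at both days, as do the 6 genes on chromosome 8, of which 6 were called in the stem on each day, 0 in the day 6 crown and 1 in the day 9 crown.

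Among genes listed in both regions, drought responses of crown and stem went mostly in the same direction at day 9. Of 1274 genes called in the crown, 851 were listed in both comparisons, and the rest have no stem sign. Of the 851, 93.1% had the same sign in the stem (95% interval 91.1 to 94.7). Of 646 genes called in the stem and listed in both, 95.5% had the same sign in the crown. Shared calls numbered 70 higher genes, where independent lists would share 3.29 (Fisher's exact test, odds ratio 41.4), and 225 lower genes against 14.1 (odds ratio 52.4). The 2 genes called lower in the crown and higher in the stem, chosen after their values were seen, were Sevir.8G210100 (chromosome 8, 34499523 to 34501272) and Sevir.9G542800 (chromosome 9, 53335846 to 53337900). In the authors' deposited tables their log2 fold changes were -0.97 and -3.64 in the crown and 1.07 and 2.98 in the stem. No gene was higher in the crown and lower in the stem, where 6.29 would be expected of independent lists (Fisher's exact test, adjusted p = 0.00436). For genes called in the crown, the median log2 fold change in the authors' deposited tables was 1.30 in the crown and 0.72 in the stem for higher genes, and -1.31 and -0.83 for lower genes. Genes picked by their crown value are expected to be larger there, and the reverse selection gave 1.39 in the stem and 0.64 in the crown for higher genes. Crown and stem came from the same repeats and harvests, and the numbers expected of independent lists leave out any deviation of the plants common to both. The interaction of drought with region was not tested, because library values are needed for it.

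**Figure D3:**
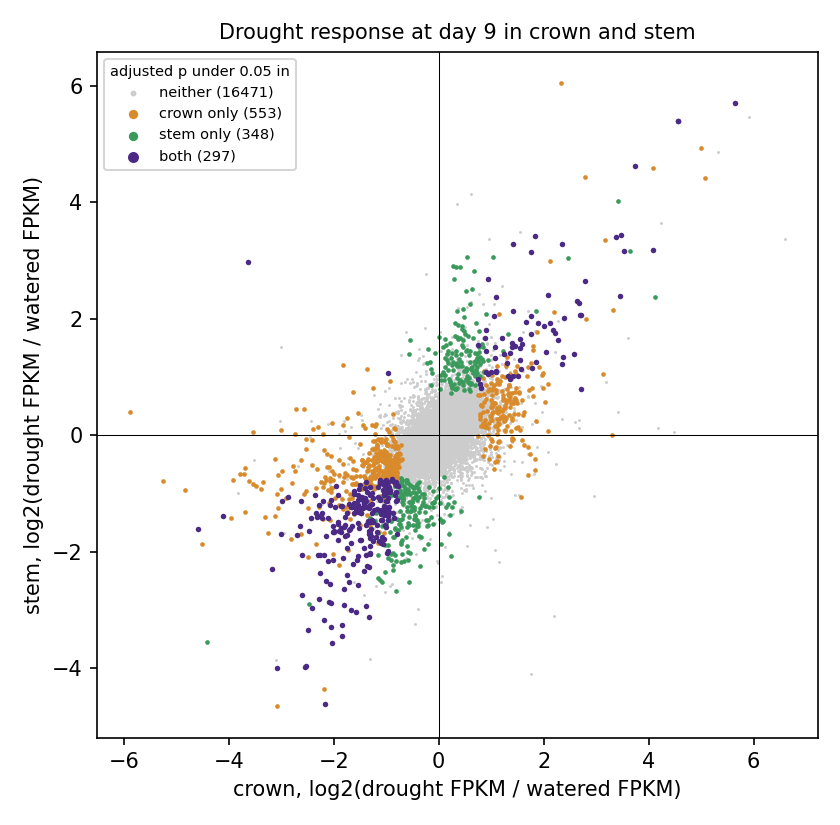
Log2 ratio of drought to watered FPKM at day 9 in crown (horizontal axis) and stem (vertical axis) for 17669 genes with a finite ratio in both, coloured by the comparison in which the authors' adjusted p was under 0.05. Of the plotted genes, the 297 called in both lie mostly along the diagonal, 553 were called in the crown only and 348 in the stem only.

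Between days, the crown responses also shared genes. Of 910 genes called at day 9 and listed at both days, 84.9% had the same sign at day 6 (95% interval 82.5 to 87.2), with 49 shared higher genes against 1.63 expected (Fisher's exact test, odds ratio 74.9) and 143 shared lower genes against 9.31 (odds ratio 38.8). The median log2 fold change of the day 9 lower genes was -1.29 at day 9 and -0.61 at day 6 in the authors' deposited tables, and that of the day 6 lower genes was -1.26 at day 6 and -0.94 at day 9. In the stem, 54 higher genes were shared against 0.951 expected (Fisher's exact test, odds ratio 195) and 61 lower genes against 3.16 (odds ratio 37.7). The interaction of drought with day in the crown was not tested.

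Crown and stem differed in many more genes than drought and watered groups. At day 6 in watered plants, Sevir.9G554700 (chromosome 9, 54116602 to 54119120) stood at 17.0 FPKM in the crown and 0.108 in the stem, and Sevir.8G220300 (chromosome 8, 35716036 to 35717735) at 353 and 5.59 FPKM, with log2 fold changes of 7.30 (q = 0.0232) and 5.98 (q = 0.00091) in the authors' deposited table. Sevir.1G257200 (chromosome 1, 32128209 to 32131952) and Sevir.9G291500 (chromosome 9, 30801858 to 30803019) were lower in the crown, with log2 fold changes of -5.53 and -5.30 in the authors' deposited table. At day 9, Sevir.6G223800 (chromosome 6, 32674024 to 32676224) reached 70.3 FPKM in the watered crown against 0.377 in the stem, a log2 fold change of 7.54 in the authors' deposited table (q = 0.00091). Under drought at day 9, Sevir.4G196200 (chromosome 4, 29280547 to 29282542) stood at 219 FPKM in the crown and 0.544 in the stem, a log2 fold change of 8.65 in the authors' deposited table (q = 0.00472). Sevir.6G180400 (chromosome 6, 29189839 to 29190478) was among the falls named by the rule in the crown relative to the stem at day 9 with and without drought, at 22.6 against 403 FPKM in watered plants and 12.8 against 333 FPKM under drought. In watered plants 1546 genes were higher and 2283 lower in the crown at day 6, and 2337 and 1341 at day 9. Under drought the numbers were 1191 and 1986 at day 6, and 2285 and 1307 at day 9. More genes were thus higher in the stem at day 6 and in the crown at day 9 in both water regimes. The day 9 excess did not hold among genes at or above the median mean FPKM, of which 886 were higher and 917 lower in watered crowns, and 791 higher and 934 lower in drought crowns.

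Watered and drought plants had largely matching region differences. At day 6, 832 crown-higher and 1698 crown-lower genes were called in both, against 94.5 and 248 expected of independent lists, and 0 genes were called in opposite directions. At day 9 the shared numbers were 1472 and 958, against 236 and 92.1 expected, and 4 genes were higher in the watered crown and lower in the drought crown. Between day 6 and day 9 in watered plants, 649 crown-higher genes were shared against 156 expected (Fisher's exact test, odds ratio 9.44) and 1054 crown-lower genes against 162 (odds ratio 51.1).

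From day 6 to day 9 more genes rose than fell in the crown, and more fell than rose in the stem. In watered plants 228 genes rose in both regions, against 49.5 expected of independent lists, and 64 rose in the crown and fell in the stem, against 71.2 expected (Fisher's exact test, odds ratio 0.886, adjusted p = 0.444). In watered crowns, Sevir.8G230200 (chromosome 8, 36923979 to 36924576) rose from 1.17 to 78.8 FPKM and Sevir.2G371800 (chromosome 2, 42580352 to 42581619) from 0.856 to 49.5 FPKM, with log2 fold changes of 6.08 (q = 0.0277) and 5.85 (q = 0.00091) in the authors' deposited table. Sevir.2G057600 (chromosome 2, 4524401 to 4525226) fell from 44.1 to 8.78 FPKM in watered crowns and from 72.3 to 4.84 FPKM in drought stems, log2 fold changes of -2.33 and -3.90 in the authors' deposited tables (both q = 0.00091). In watered stems, Sevir.3G352200 rose from 0.434 to 20.4 FPKM, a log2 fold change of 5.55 in the authors' deposited table (q = 0.0331). It was lower under drought at day 9, as given above, in a comparison that uses the same watered day 9 stem value. In drought stems, Sevir.8G210100 rose from 2.15 to 142 FPKM, a log2 fold change of 6.05 in the authors' deposited table (q = 0.00091). In watered crowns 1661 genes rose and 388 fell, so that 18.9% fell (95% interval 17.3 to 20.7), and in drought crowns 1553 rose and 504 fell (24.5%). Among genes at or above the median mean FPKM, 29.0% fell in watered crowns (644 rose, 263 fell) and 40.9% in drought crowns (533 rose, 369 fell). In watered stems 801 rose and 1227 fell, and in drought stems 744 rose and 1329 fell. For the watered stem, 53.5% of genes above 0 FPKM on both days and at least 2-fold apart were lower at day 9, and 47.6% after centring on the median gene. Age changes with and without drought shared 792 rising and 198 falling genes in the crown, against 106 and 10.4 expected, and 372 rising and 790 falling genes in the stem, against 28.8 and 90.8.

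Genes set apart by region or age in watered plants were followed into drought comparisons that use other libraries of the same 3 repeats. Random lists do not account for deviations that crown and stem of a harvest have in common. The 1366 crown-higher genes of day 6 had a median log2 fold change of 0.28 under drought in the day 9 stem, above all of 10000 random lists matched on mean FPKM, and 113 of them were called higher, 54 lower and 1199 neither. Both shares were above those of the other genes, at 8.27% against 0.56% called higher and 3.95% against 2.12% called lower. Among the 1366, 45 genes called over 8-fold higher in the crown, with at least 20 FPKM in the drought day 9 crown, had a median of 1.32, and their drought stem level was at a median of 24.4% of the crown level. The 2196 stem-higher genes had a median of -0.32, below all random lists, with 8 higher and 95 lower. In the day 9 crown the medians were 0.12 for 1537 crown-higher genes (94 higher, 80 lower) and -0.21 for 2086 stem-higher genes (20 higher, 143 lower). At day 6, with sets defined at day 9, crown-higher genes had a median of -0.22 in the stem (24 of 1402 higher, 56 lower) and -0.07 in the crown (29 of 1858 higher, 120 lower). The crown value lay below all random lists. Among genes at or above the median mean FPKM it became 0.0061, above all of their random lists, of which fewer than 10000 were drawn. No direction is therefore given for this set. Stem-higher genes of day 9 had medians of -0.20 in both regions.

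Of the 1095 genes that rose with age in watered crowns, 219 were lower and 19 higher under drought in the day 9 stem, that is 20% lower against 1.25% of the other genes (Fisher's exact test, odds ratio 19.8, adjusted p = 3.34e-151). Their median log2 fold change was -0.47, below all random lists. The watered day 9 crown that defines the set and the watered day 9 stem in this comparison came from the same repeats and harvest. The 376 genes that fell with age in the crown had a median of -0.35, and 26 of them were called lower, 0 higher and 350 neither. In the day 6 stem the medians of genes rising and falling with age in the crown were -0.31 (60 of 910 lower, 7 higher) and -0.21 (13 of 382 lower, 1 higher). Genes rising with age in watered stems had medians of -0.03 in the day 6 crown (8 of 760 higher, 63 lower), inside the central 95% of the random lists, and of -0.10 in the day 9 crown (11 of 789 higher, 60 lower). In the day 6 crown they were still called lower more often, 8.29% against 1.26% of the other genes (Fisher's exact test, odds ratio 7.09, adjusted p = 9.33e-28). Called higher were 1.05% of them against 0.36% of the other genes. Genes falling with age in watered stems had medians of -0.24 (1 of 1127 higher, 62 lower) and -0.19 (27 of 1114 higher, 127 lower). Of the 16 set medians, 14 were below 0.

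**Figure D4:**
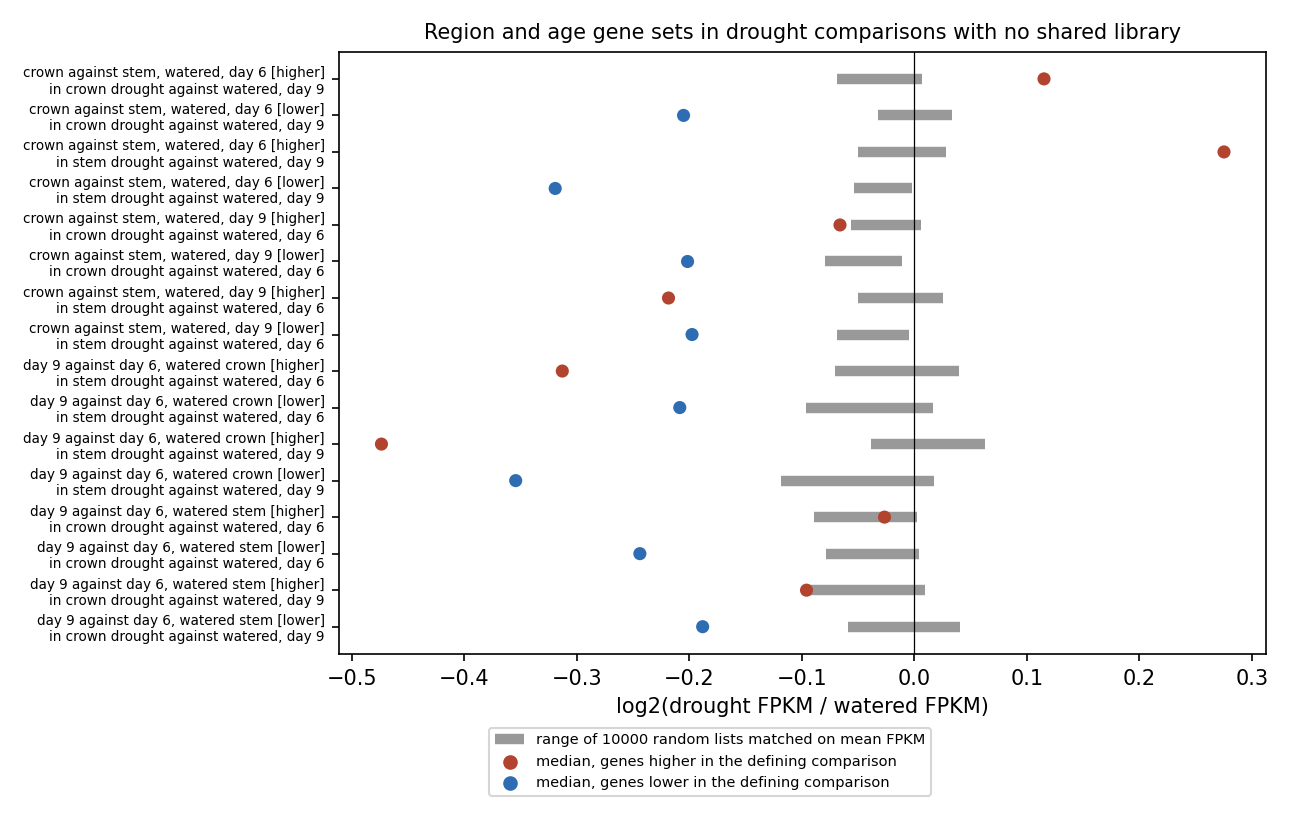
Median log2 ratio of drought to watered FPKM (horizontal axis) of gene sets defined by region or age in watered plants, each in a drought comparison that shares no library with its definition, with red points for genes higher and blue points for genes lower in the defining comparison. Grey bars span 10000 random lists matched on mean FPKM, and 14 of the 16 medians lie outside them, from -0.47 to 0.28, of which that of crown-higher genes of day 9 in the day 6 crown changed sides among genes at or above the median mean FPKM.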

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

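The alternatives for overlaps and gene sets were chosen after the data were seen, those for counts before. All 22 overlaps of calls in the same direction kept an odds ratio above 1 and their side of the threshold under each of 4 alternatives (from 6.20 to 1610). Among genes listed in both comparisons, the share of day 9 crown calls with the same sign stayed between 92.9% and 93.6% in the stem and between 84.4% and 87.1% at day 6. At an adjusted p under 0.01, drought comparisons called 140 genes (crown, day 6), 661 (crown, day 9), 80 (stem, day 6) and 287 (stem, day 9), crown against stem 2348 and 1992 (watered and drought, day 6) and 2250 and 2229 (day 9), and day 9 against day 6 991 and 1054 (watered and drought crown) and 846 and 1016 (stem). Among genes at or above the median mean FPKM, in the same order, the counts were 186, 588, 109, 277, then 2194 and 1785, 1803 and 1725, then 907 and 902, 1183 and 1247. Both follow from a stricter limit and from fewer genes. Adjusted within each table, 95 (crown, day 6), 36 (stem, day 6) and 280 genes (stem, day 9) passed, since small p-values of other tables no longer enter. With a minimum of a 2-fold change, 1348 genes passed for the age of the watered stem. Among genes at or above the median mean FPKM, crown-higher genes of day 9 moved from -0.07 to 0.0061 in the day 6 crown, from below to above all random lists, genes rising with age in the stem from -0.03 to 0.015 (0.011 with the set called at an adjusted p under 0.01), which put them outside the central 95% of random lists, and their day 9 value from -0.10 to -0.11, now inside; the cause was not tested. Among genes above 0 FPKM in both groups, centring on the median gene moved the share of lower genes at least 2-fold apart by less than 10 points in every comparison. The centred share lay outside the 95% interval of the uncentred share in 5 comparisons and inside it in 7. For the age of the watered stem it went from 53.5% to 47.6%, so that the direction changed. No paired analysis was possible because the deposited tables carry 1 value per group and no library. For the same reason leaving out replicates, other normalizations, count models, pseudocounts, a fit of fewer groups and no filter were not run, and neither were alternatives of the gene lists, which had 0 members. Depth per library is unknown, so its limit on low genes was not measured.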

Other observations

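Tests against overlapping gene models, similar expression of neighbours, the scaling offset, the expression level of gene sets, and low expression outside the day 6 stem were chosen only after the result was seen. On chromosome 9, the 6 listed genes between 38660698 and 38684857 (Sevir.9G351100 to Sevir.9G351800) were all called lower in drought crowns at day 9. One of them was listed at 0 under drought, and the log2 fold changes of the others ran from -2.59 to -1.56 in the authors' deposited table. Sevir.9G351700 stood at 17.0 FPKM in watered and 5.11 FPKM in drought crowns at day 9, and at 2.84 FPKM in watered crowns at day 6. These genes were chosen after their values were seen.

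In the crown, 7 genes were lower under drought at day 6 and higher at day 9, where independent lists would share 5.17 (Fisher's exact test, adjusted p = 0.415), and they were chosen after their values were seen. Among them, Sevir.8G121100 (chromosome 8, 20258230 to 20259723) went from 3.58 FPKM in watered to 0.363 FPKM in drought crowns at day 6 and from 8.44 to 26.9 FPKM at day 9. Sevir.9G555500 (chromosome 9, 54153527 to 54154290) went from 5.78 to 1.05 FPKM at day 6 and from 4.15 to 18.4 FPKM at day 9. Their number was somewhat above that expected of independent lists, and the test did not tell the 2 apart. The lists of both days shared many calls in the same direction, so this expectation cannot show whether 7 is a chance number. The difference between days was not tested.

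Neighbouring genes changed together under drought. In the day 9 crown, 141 pairs of neighbours were called in the same direction, against a mean of 42.1 in permutations, and the other comparisons had 27 against 4.76 (crown, day 6), 17 against 1.87 (stem, day 6) and 48 against 12.3 (stem, day 9), each at a permutation p = 0.0001, the smallest these permutations can give. Similar expression of neighbours is argued against, since calls were permuted within bins of mean FPKM and the lowest ratio was 3.35. Overlapping or merged gene models are argued against by pairs at least 5000 bp apart, for which the lowest ratio of observed to permuted pairs was 4.21. Reads shared between similar copies side by side could give the same pattern and stay open, as do drought responses shared along a chromosome, because no sequence was used here to tell copies from other genes.

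In the day 9 stem, the set medians under drought were 0.28 for crown-higher genes, -0.32 for stem-higher genes and -0.47 for genes that rise with age in the watered crown, though most members of each set were not called; the expression level of the age set is argued against, since the lowest random list had a median of -0.039. Less crown tissue in the drought stem samples is argued against by 521 genes as crown-rich as the risen genes (watered day 9 crown over watered day 6 stem) that did not rise with age, with a median of 0.58 (95% bootstrap interval 0.49 to 0.64) where 550 risen genes had -0.69, and 501 of the 521 were also above the stem in watered day 9 plants. Relative to the watered day 9 stem the 521 were less crown-rich, at a median log2 ratio of 1.16 where the 550 had 1.57. The 168 of them that reached the median of the 550 there too had a median log2 fold change of 0.73. The watered day 9 stem level that picked these 168 also enters their fold change, so this value adds no separate evidence. The check on the 521 genes is not independent of the rise of crown-higher genes, which had been seen before. Neither of the other checks decided: 78 risen genes with a watered day 9 crown level at or below the watered day 6 stem level had a median of -0.46, but only 19 of them were also at or below the watered day 9 stem level, and the 13 genes at or below the drought day 9 stem level (median 0.42, interval -0.36 to 1.07) were picked by a level that enters their fold change. More crown tissue as the whole cause is argued against by the 45 genes over 8-fold higher in the crown, whose stem level had a lower quartile of 14.4% of the crown level (interval 10.1 to 17.8) where a share of 42.7% would be needed for the median rise, although their own median of 1.32, with 1.99 predicted at that share, goes with some crown tissue. It is also argued against by 859 risen genes whose drought day 9 crown level was above the watered day 9 stem level. More tissue at the group level of the drought day 9 crown would not alone lower these genes, and their median was -0.35 (interval -0.40 to -0.30). The checks against more crown tissue take added tissue at that level, and no part of the crown was measured apart. A smaller share of crown tissue, loss of a part of the crown rich in risen genes, deviations common to the watered crown and stem of the day 9 harvest, and an effect of drought on the timing of development, which no test here addressed, may each contribute and stay open.

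More genes were lower than higher under drought in the 4 comparisons, though under the stricter limits on p this did not hold in the day 6 stem. Low expression as the cause is argued against in the other 3, where at least 67.9% of calls at or above the median mean FPKM were lower (lowest lower limit 62.0%). In the day 6 stem the share was 63.3% (95% interval 53.5 to 72.3), too wide to decide. A scaling offset was not tested on the calls and stays open, since the authors' scaling puts the median gene near 0. Over listed genes above 0 FPKM in both groups and at least 2-fold apart, called or not, the lower share was 69.8% and 55.1% in the crown (day 6 and day 9) and 60.7% and 60.6% in the stem, and an offset between 0.07 and 0.17 on the log2 scale would equalise those numbers, not those of the calls. No count of other splits of the samples could be made from group values. Whether drought itself lowers more genes than it raises stays open.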
